A study of Mus musculus with 8 samples.

How the data were processed

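TT-seq libraries of newly made RNA from E14 mouse embryonic stem cells were compared between wildtype cells (3 libraries), single-targeted H3.3 K122A lines (2) and dual-targeted lines (3). The labels describe media with LIF and with LIF and 2 inhibitors, without saying which was used for these libraries. The labels call the wildtype libraries biological replicates, while each mutant line gave a single library. Processing by the submitters named STAR, SAMtools, featureCounts, DESeq2 and deepTools and the builds mm10 and GRCm38.p6, per the submitters' processing notes, which give no versions. The use of strand in counting is not given in the sources used here, so overlapping and antisense genes are uncertain.

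The files were 4 tables of the authors' own comparisons, each normalized and fitted separately: dual-targeted against wildtype, single-targeted against wildtype, dual-targeted against single-targeted, and the 2 H3f3a A/A H3f3b WT/A clones against wildtype. The first column of values is, per the file headers, the authors' mean of normalized counts over the libraries compared. The log2 fold changes and their standard errors as deposited are read here as shrunken values, since for 100% of the called genes the fold change was smaller than its p implies with the deposited error. The estimator behind the shrinkage is not given in the sources used here, and shrinkage differs between tables, so the sizes of fold changes in different tables are not strictly comparable. The p-values and the adjusted p-values were made by the authors before deposit, per the file headers. An empty adjusted p was kept empty. The tables held 16498, 16255, 16149 and 16254 genes, of which 16493, 15030, 13141 and 15640 had an adjusted p. No column of values per library was used, so the depth per library is unknown and its precision enters only through the authors' standard errors. The median of the mean count lay at 144, 153, 142 and 157 in the 4 tables, and the lowest at 6.18, 7.07, 6.65 and 7.08.

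The direction of the deposited fold changes was settled from reconstructed group means. With 4 means over known numbers of libraries, the means of the wildtype, single-targeted and dual-targeted groups, of the clones and of the H3f3a WT/A H3f3b A/A line follow by subtraction. For 100% of 2726, 387, 885 and 2504 called genes that were in all 4 tables and had a mean count of 50 or more, these means had the same sign as the fold change, where positive is higher in the mutant group, or in the dual-targeted group against the single-targeted. This method was chosen after the files were seen, in place of those planned. To join separately normalized tables, scales of 0.987, 1.06 and 0.957 were set so that the median gene of each group equals wildtype, also chosen after the data were seen. The median log2 ratio of the H3f3a WT/A H3f3b A/A line, which was not set directly, was -0.01, and 2 of 15571 genes came out below 0. That median follows largely from those set for the dual-targeted group and the clones, so it is no independent check. Reconstructed means carry no error.

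The comparisons, 30 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. A gene was called at an adjusted p under 0.05. Named genes were H3f3a and H3f3b, the 8 largest rises and 8 largest falls among called genes with a mean count of 50 or more (leaving out predicted or unnamed genes), and up to 4 members of each list by adjusted p. Gm26917, Gm42418, Gm10060, Thbs1, Tagln, Mir6236, mt-Rnr1 and mt-Rnr2 were named after their values were seen. Lists were tested with cameraPR in limma 3.58.1 (R 4.3.3) at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison. The plan was the fold change over its standard error, but the fold changes are shrunken, so a signed z was computed from the deposited p (values under 1e-300 were set to it) and the sign of the fold change. A correlation could not be estimated without values per library, and 0.05 was tried. List medians have percentile intervals from 2000 bootstrap draws of members. The correlation of the 2 comparisons with wildtype that shared wildtype libraries alone would give was simulated with unchanged groups.

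Gene positions, types and lengths came from the GENCODE mouse annotation, release 21 of the GRCm38 series, which held 98.7% of the symbols. Chromosome medians used genes with a mean count of 50 or more, set against 10000 random gene sets. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The list tests and the reconstruction were tested on simulated data. For the dual-targeted comparison with wildtype (16493 genes) 4 of 5 shifted lists of 10 or more members were called, and 0 of 14 unshifted lists. The simulated genes were independent of each other and otherwise unchanged. This checks that the code runs as meant, and does not give the rate of false calls among correlated genes. In the reconstruction over 15571 genes with 200 changed, the median absolute log2 error was 0.0194 in the single-targeted group, 0.0249 in the clones and 0.0575 in the H3f3a WT/A H3f3b A/A line. The largest errors were 0.443, 0.329 and 1.16 in the same order, so a value of a single gene in that line can be off by more than 1 on the log2 scale.

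Alternatives were other thresholds, a minimum fold change, adjustment over every gene with a p, a minimum mean count, centred fold changes, ranks, Fisher's exact test of called members and the clones in place of the 3 dual-targeted lines. Leaving out chromosomes 8, 14 and Y and taking out the trend with gene length were added after the data were seen. A sign change of a list or gene that was called in neither setting was not counted as a reversal.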

Results

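TT-seq measures the RNA that cells make during a short pulse of 4-thiouridine (4sU), a uridine analogue that enters new transcripts and lets them be drawn out of total RNA. The cells were ES-E14TG2a (E14), a mouse embryonic stem cell line of male origin, pulsed with 500 nM 4sU for 5 min. They carried the K122A substitution (lysine to alanine) in histone H3.3, the H3 variant that is placed into chromatin outside DNA replication. H3.3 is encoded by H3f3a and H3f3b, so a diploid cell has 4 alleles. The 8 libraries fell into 3 groups. Wildtype cells gave 3 libraries from biological replicates. The single-targeted group held 2 lines with 2 mutant alleles each, H3f3a A/A H3f3b WT/WT and H3f3a WT/WT H3f3b A/A. The dual-targeted group held 3 lines with 3 mutant alleles each. Of these, 2 were clones of the genotype H3f3a A/A H3f3b WT/A, and the third was H3f3a WT/A H3f3b A/A. Each of the 5 mutant lines was profiled a single time, so the spread within a mutant group is a spread between lines. The values come from 4 tables of the authors' own comparisons, and values per library were not analysed here. The depth of each library is therefore unknown. Mean normalized counts summed to 1.26e+07 in the authors' deposited table of the dual-targeted and wildtype groups, and to 1.08e+07 in that of the single-targeted and wildtype groups.

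The targeted genes were read first, although an amino acid substitution need not alter transcript level and so does not check the labels. H3f3a (chromosome 1, 180800832 to 180813943, GRCm38) had a log2 fold change of 0.13 ± 0.19 (SE) in dual-targeted lines in the authors' deposited table (adjusted p = 0.633). In single-targeted lines the authors' deposited table gave -0.12 ± 0.18 for H3f3a (adjusted p = 0.674). H3f3b (chromosome 11, 116021912 to 116027962) stood at 0.06 ± 0.36 in dual-targeted lines (adjusted p = 0.8) and at -0.01 ± 0.17 in single-targeted lines (adjusted p = 0.908) in the authors' deposited table. In the H3f3a A/A H3f3b WT/A clones alone, H3f3b was higher than in wildtype in the authors' deposited table, at 0.84 ± 0.27 (adjusted p = 0.00351). Group means rebuilt from the tables, which carry no error, put H3f3b at 2523 normalized counts in wildtype, 4833 in these clones and 364 in the H3f3a WT/A H3f3b A/A line.

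Dual-targeted lines were set against wildtype cells to ask how labelled RNA differed once 3 of the 4 H3.3 alleles were mutant. Among the 8 largest rises in the authors' deposited table were Cd200 (log2 fold change 5.46 ± 1.69 SE, adjusted p = 8.04e-04), a membrane glycoprotein, and Adgrg6 (4.09 ± 0.39, adjusted p listed as 0), an adhesion G protein-coupled receptor. Socs3 (3.32 ± 0.28, adjusted p listed as 0), an inhibitor of the JAK-STAT signalling that LIF drives, was also among them in the authors' deposited table. The 8 largest falls in the authors' deposited table included Lrrc31 (-3.93 ± 0.26, adjusted p listed as 0), Acss1 (-3.58 ± 0.27, adjusted p listed as 0), which makes acetyl-CoA from acetate, and Cers1 (-2.49 ± 0.36, adjusted p = 4.16e-11), a ceramide synthase. Ribosomal protein genes, p53 targets, core pluripotency genes, heat shock genes, outputs of the ERK pathway and mitochondrially encoded genes rose as groups, and replication-dependent histone genes fell, with the counts and tests given next. In all, 1785 genes were higher and 1659 lower in dual-targeted lines at an adjusted p under 0.05 in the authors' deposited table. Without chromosomes 8, 14 and Y, 1698 were higher and 1273 lower, and with the trend of fold change on gene length taken out 1526 were higher and 1763 lower. The other genes named by size that rose in the authors' deposited table were Catip (4.31 ± 0.58), Creb5 (3.83 ± 0.34), Rbfaos (3.69 ± 0.39), Soga3 (3.52 ± 0.29) and the long noncoding RNA Miat (3.18 ± 0.26). Those that fell in the authors' deposited table were Crispld1 (-2.81 ± 0.41), Patl2 (-2.73 ± 0.38), Nudt12 (-2.46 ± 0.43), the fatty acid elongase Elovl7 (-2.45 ± 0.33) and the fibroblast growth factor Fgf1 (-2.42 ± 0.28). An adjusted p listed as 0 is below the precision of the authors' deposited table.

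Ribosomal protein genes had a median log2 fold change of 0.52 (95% interval 0.46 to 0.59) in dual-targeted lines. They were higher at 50 of 87 members and lower at 0 (68 and 0 when adjusted over the list alone, list test adjusted p = 1.76e-10). The authors' deposited table held Rpl30 (0.82 ± 0.18, adjusted p = 4.21e-05) and Rpl9 (0.80 ± 0.20, adjusted p = 3.13e-04), both of the large ribosomal subunit. In the same comparison Gm26917 (0.89 ± 0.23, adjusted p = 2.55e-04) and its neighbour Gm42418 (0.86 ± 0.25, adjusted p = 0.00154) rose in the authors' deposited table. Both are annotated as long intergenic RNA genes. There shorter genes were higher (Spearman's rho -0.293 across 10019 protein-coding genes, which are not independent replicates). Features inside introns lay below their host genes by a median log2 difference of -0.10. Of 25 p53 targets, 15 were higher and 0 lower (15 and 0 when adjusted over the list alone, median 0.58, list test adjusted p = 1.11e-09). They included Plk2 (2.17 ± 0.22, adjusted p listed as 0), a polo-like kinase, and Ccng1 (1.14 ± 0.19, adjusted p = 2.52e-08), cyclin G1, in the authors' deposited table. Core pluripotency genes were higher at 9 of 14 members and lower at 0 (11 and 0 when adjusted over the list alone, median 0.51, list test adjusted p = 7.28e-04). The authors' deposited table gave Pou5f1 (0.75 ± 0.21, adjusted p = 0.00113), which encodes OCT4, and Sall4 (0.83 ± 0.19, adjusted p = 5.08e-05). Of 11 heat shock genes, 7 were higher and 0 lower (8 and 1 when adjusted over the list alone, median 0.48, list test adjusted p = 4.84e-04). Among these were Hsph1 (1.30 ± 0.17, adjusted p = 2.43e-12) and the mitochondrial chaperonin Hspd1 (1.03 ± 0.20, adjusted p = 1.08e-06) in the authors' deposited table. ERK outputs were higher at 8 of 14 members and lower at 0 (8 and 0 when adjusted over the list alone, median 0.65, list test adjusted p = 0.00148). Members that rose in the authors' deposited table were Etv4 (1.86 ± 0.27, adjusted p = 5.93e-11), an ETS factor, and Spry2 (1.00 ± 0.22, adjusted p = 1.75e-05), a feedback inhibitor of receptor tyrosine kinases. Of 19 mitochondrially encoded genes, 10 were higher and 0 lower (10 and 0 when adjusted over the list alone, median 1.03, list test adjusted p = 1.33e-21). The transfer RNA genes mt-Tp (2.07 ± 0.24, adjusted p = 1.00e-16) and mt-Tw (2.36 ± 0.28, adjusted p = 1.00e-15) were among them in the authors' deposited table.

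Replication-dependent histone genes, which are made in S phase to package new DNA, had a median log2 fold change of -0.54 (95% interval -0.82 to -0.45) in dual-targeted lines. They were lower at 30 of 61 members and higher at 0 (32 and 0 when adjusted over the list alone, list test adjusted p = 1.31e-07). Hist1h2ac (-1.62 ± 0.26, adjusted p = 2.74e-09) and Hist1h2bg (-1.34 ± 0.22, adjusted p = 1.09e-08) were among them in the authors' deposited table, and both are uncertain as single genes because near-identical histone copies can share reads. Formative and primed pluripotency genes were higher at 4 of 13 members and lower at 2 (4 and 3 when adjusted over the list alone, median 0.12, list test adjusted p = 4.81e-05). In the authors' deposited table Lef1 (1.80 ± 0.21, adjusted p = 1.40e-15) and Foxd3 (2.34 ± 0.30, adjusted p = 8.82e-14) rose and Zic2 (-1.14 ± 0.21, adjusted p = 7.34e-07) fell. On ranks of the statistic the formative list was not called (adjusted p = 0.357), nor by Fisher's exact test of called members (adjusted p = 0.0963). Of its members, Otx2 and Sall2 lie in the stretch of chromosome 14 that was lower in the clones, and Zic2 and Zic5 lie on that chromosome outside it. Naive pluripotency genes were higher at 2 of 14 members and lower at 2 (2 and 2 when adjusted over the list alone, median 0.03, list test adjusted p = 0.994). In the authors' deposited table Klf4 (1.08 ± 0.20, adjusted p = 3.59e-07) and Klf5 (0.99 ± 0.18, adjusted p = 4.59e-07) rose while Tcl1 (-1.60 ± 0.23, adjusted p = 5.26e-11) and Klf2 (-1.08 ± 0.27, adjusted p = 1.24e-04) fell.

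Genes of other lineages were not called as lists in dual-targeted lines. Neural ectoderm had 2 of 7 higher and 0 lower, 2 and 0 when adjusted over the list alone, median -0.02, adjusted p = 0.626. Its members Nes (1.91 ± 0.85, adjusted p = 0.00802), the intermediate filament nestin, and Tubb3 (1.07 ± 0.28, adjusted p = 2.79e-04), a neuronal tubulin, rose in the authors' deposited table. Mesoderm and primitive streak had 1 of 4 higher and 0 lower, 1 and 0 when adjusted over the list alone, median 0.11, adjusted p = 0.624. Endoderm had 2 of 9 higher and 0 lower, 2 and 0 when adjusted over the list alone, median 0.07, adjusted p = 0.445. Lamb1 (1.43 ± 0.21, adjusted p = 2.75e-10), a laminin chain, rose in the authors' deposited table. Trophectoderm had 1 of 6 higher and 0 lower, 1 and 1 when adjusted over the list alone, median 0.00, adjusted p = 0.897. Fibroblast and feeder genes had 1 of 4 higher and 2 lower, 1 and 2 when adjusted over the list alone, median -0.10, adjusted p = 0.624. Fibronectin, Fn1 (-1.01 ± 0.18, adjusted p = 3.46e-07), fell in the authors' deposited table. Germline genes had 7 of 20 higher and 0 lower, 7 and 0 when adjusted over the list alone, median 0.32, adjusted p = 0.0522. Imprinted genes had 7 of 25 higher and 1 lower, 9 and 1 when adjusted over the list alone, median 0.19, adjusted p = 0.0522. The imprinted genes Peg10 (2.00 ± 0.27, adjusted p = 1.28e-12) and Cdkn1c (2.01 ± 0.34, adjusted p = 2.65e-08) rose in the authors' deposited table. Of the 2-cell-like list, 2 multi-copy genes were measured, Zscan4a (6.42 ± 1.41, adjusted p = 4.98e-06) and Usp17le (6.15 ± 1.94, adjusted p = 8.13e-04) in the authors' deposited table, and the list test missed the threshold (2 of 2 higher and 0 lower, 2 and 0 when adjusted over the list alone, median 6.29, adjusted p = 0.0522). These 2 are uncertain, with near-identical copies and mean counts of 18.7 for Zscan4a and 19.8 for Usp17le in the authors' deposited table. Of the Hox genes a single member was measured, Hoxb9 (0.74 ± 0.58, adjusted p = 0.0816) in the authors' deposited table.

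H3.3 chaperone genes had 1 of 12 higher and 1 lower, 1 and 1 when adjusted over the list alone, median 0.17, adjusted p = 0.624. In the authors' deposited table Asf1a (0.73 ± 0.20, adjusted p = 0.00106) rose and Ubn1 (-0.61 ± 0.18, adjusted p = 0.00233) fell. Genes for histone acetylation were not called as a list (median 0.03, adjusted p = 0.948). Interferon response genes had 3 of 8 higher and 3 lower, 3 and 3 when adjusted over the list alone, median -0.01, adjusted p = 0.939. Ifitm3 (2.22 ± 0.34, adjusted p = 5.19e-10) rose and Stat2 (-1.03 ± 0.21, adjusted p = 5.86e-06) fell in the authors' deposited table. Glycolysis and hypoxia genes had 5 of 19 higher and 5 lower, 7 and 6 when adjusted over the list alone, median 0.26, adjusted p = 0.939. Hk2 (0.86 ± 0.17, adjusted p = 5.11e-06), hexokinase 2, rose and Egln3 (-1.72 ± 0.30, adjusted p = 7.02e-08), an oxygen-sensing prolyl hydroxylase, fell in the authors' deposited table. The integrated stress and unfolded protein response had 2 of 24 higher and 3 lower, 2 and 3 when adjusted over the list alone, median 0.03, adjusted p = 0.98. Immediate early genes had 2 of 12 higher and 0 lower, 2 and 0 when adjusted over the list alone, median 0.35, adjusted p = 0.135. Wnt, BMP and Nodal targets had 5 of 17 higher and 2 lower, 6 and 4 when adjusted over the list alone, median 0.10, adjusted p = 0.612. The cell cycle had 3 of 28 higher and 2 lower, 3 and 0 when adjusted over the list alone, median 0.12, adjusted p = 0.5. DNA methylation genes had 2 of 8 higher and 0 lower, 2 and 0 when adjusted over the list alone, median 0.14, adjusted p = 0.347. Extracellular matrix and adhesion genes had 5 of 16 higher and 1 lower, 5 and 1 when adjusted over the list alone, median 0.22, adjusted p = 0.203, and Sparc (1.69 ± 0.22, adjusted p = 9.91e-13), a matrix glycoprotein, rose in the authors' deposited table. Y-linked genes had 1 of 4 higher and 0 lower, 1 and 0 when adjusted over the list alone, median -0.06, adjusted p = 0.98. Small nucleolar RNA genes had 6 of 56 higher and 2 lower, 5 and 1 when adjusted over the list alone, median 0.15, adjusted p = 0.203. The list tests used a preset correlation between genes, since none could be estimated from these tables, and all 8 calls held when it was raised to 0.05. Members that move together more than that, as adjoining mitochondrial genes may, would make these p-values too small.

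Single-targeted lines were set against the same wildtype libraries to ask what differed with 2 mutant alleles. Mitochondrial transcripts were prominent among the 8 largest rises in the authors' deposited table, with mt-Ti (log2 fold change 3.12 ± 0.46 SE, adjusted p = 2.50e-09), an isoleucine transfer RNA, and mt-Nd1 (2.25 ± 0.62, adjusted p = 0.00175), a subunit of respiratory complex I. The nuclear gene Mdga1 (2.12 ± 0.40, adjusted p = 5.72e-06) was also among these 8 in the authors' deposited table. Falls in the authors' deposited table included Acss1 (-2.22 ± 0.25, adjusted p listed as 0) and Lrrc31 (-1.74 ± 0.24, adjusted p = 4.81e-11), which had also fallen in dual-targeted lines, and Zic2 (-1.99 ± 0.33, adjusted p = 1.02e-07), a factor of the formative state. Mitochondrially encoded genes and p53 targets rose as groups, and replication-dependent histone genes and genes of glycolysis and hypoxia fell. There were 224 genes higher and 221 lower at an adjusted p under 0.05 in the authors' deposited table. The other genes named by size in the authors' deposited table were mt-Tl1 (2.40 ± 0.42), mt-Tm (2.39 ± 0.39), mt-Tw (2.27 ± 0.28) and mt-Co2 (2.16 ± 0.36) above wildtype. Below it were Myh13 (-2.29 ± 0.41), Kctd19 (-1.71 ± 0.46), Ap3b2 (-1.66 ± 0.38), Dnah7a (-1.65 ± 0.52) and Bcl11a (-1.55 ± 0.30) in the authors' deposited table.

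Of 22 mitochondrially encoded genes, 13 were higher and 0 lower (20 and 0 when adjusted over the list alone, median 1.67, list test adjusted p = 4.67e-62). Several of these genes adjoin, as mt-Tl1, mt-Nd1 and mt-Ti do, so members are not independent. That p rests on the preset correlation and does not measure the spread between lines. Replication-dependent histone genes were higher at 0 of 59 members and lower at 12 (0 and 30 when adjusted over the list alone, median -0.29, list test adjusted p = 4.61e-22). Hist3h2a (-1.45 ± 0.29, adjusted p = 1.91e-05) and Hist1h4c (-0.98 ± 0.28, adjusted p = 0.00252) were lower in the authors' deposited table, again with uncertainty from near-identical copies. Of 19 glycolysis and hypoxia genes, 0 were higher and 5 lower (1 and 13 when adjusted over the list alone, median -0.43, list test adjusted p = 1.08e-09). They included Pfkl (-0.79 ± 0.30, adjusted p = 0.0187), a phosphofructokinase, and Pdk1 (-0.55 ± 0.19, adjusted p = 0.0163), which restrains pyruvate entry into the citric acid cycle, in the authors' deposited table. Of 25 p53 targets, 7 were higher and 0 lower (9 and 0 when adjusted over the list alone, median 0.14, list test adjusted p = 1.47e-10). Plk2 (1.69 ± 0.27) and Mdm2 (0.64 ± 0.18), the ubiquitin ligase of p53, rose in the authors' deposited table. Other upward shifts were called for germline genes (1 of 18 higher and 0 lower, 6 and 0 when adjusted over the list alone, median 0.15, adjusted p = 7.03e-07) and imprinted genes (3 of 22 higher and 0 lower, 5 and 0 when adjusted over the list alone, median 0.06, adjusted p = 5.87e-04). The same direction was called for the integrated stress and unfolded protein response (1 of 24 higher and 0 lower, 2 and 0 when adjusted over the list alone, median 0.11, adjusted p = 4.79e-04) and Y-linked genes (1 of 4 higher and 0 lower, 3 and 0 when adjusted over the list alone, median 0.56, adjusted p = 0.00415). Members of these lists that rose in the authors' deposited table were Mael (1.77 ± 0.70), a germline gene, Peg10 (1.31 ± 0.29), Cebpb (1.61 ± 0.43) and the Y-linked Eif2s3y (0.68 ± 0.25).

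Downward shifts in single-targeted lines were called for the cell cycle (0 of 28 higher and 2 lower, 1 and 6 when adjusted over the list alone, median -0.10, adjusted p = 0.00327), where the authors' deposited table held E2f1 (-0.61 ± 0.27, adjusted p = 0.044), a transcription factor of S-phase entry, and Mcm5 (-0.61 ± 0.20, adjusted p = 0.00867), a gene of chromosome 8, whose genes were lower as a whole. They were also called for formative and primed pluripotency genes (0 of 13 higher and 3 lower, 0 and 4 when adjusted over the list alone, median -0.10, adjusted p = 9.27e-04) and for Wnt, BMP and Nodal targets (0 of 17 higher and 2 lower, 0 and 3 when adjusted over the list alone, median -0.04, adjusted p = 0.0412). Ribosomal protein genes were not called (0 of 87 higher and 1 lower, 0 and 0 when adjusted over the list alone, median -0.02, adjusted p = 0.183), nor were core pluripotency genes (1 of 14 higher and 0 lower, 1 and 0 when adjusted over the list alone, median 0.06, adjusted p = 0.161). The formative call was absent without chromosomes 8, 14 and Y (adjusted p = 0.564), where 211 genes were higher and 119 lower in the authors' deposited table, or 63.9% higher against 50.3% over all chromosomes. That setting leaves out Otx2, Zic2 and Zic5, the list's called members, of which Zic2 and Zic5 lie outside the low stretch of chromosome 14, so the lost call does not show an effect of chromosome dosage. The Wnt, BMP and Nodal call ended at a preset correlation of 0.05 (adjusted p = 0.136), where the other 10 held. Fisher's exact test of called members did not call 6 of the 11 lists, namely imprinted genes (adjusted p = 0.0853), Wnt, BMP and Nodal targets (0.198), Y-linked genes (0.245), the cell cycle (0.332), germline genes (0.604) and the integrated stress and unfolded protein response (0.681).

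Dual-targeted lines were also set against single-targeted lines directly, which compares the groups with 3 and 2 mutant alleles without the wildtype libraries and does not separate allele number from line. Among the 8 largest rises in the authors' deposited table were Cd200 (log2 fold change 4.23 ± 2.11 SE, adjusted p = 0.0163) and Lef1 (2.64 ± 0.30, adjusted p = 3.00e-16), a transcription factor of Wnt signalling. Nefl (2.30 ± 0.65, adjusted p = 0.00205), a neurofilament protein, was also among them in the authors' deposited table. Lrrc31 (-2.04 ± 0.34, adjusted p = 2.47e-07), Tarm1 (-2.01 ± 0.59, adjusted p = 0.00381) and Mid1 (-1.60 ± 0.33, adjusted p = 8.29e-05), a ubiquitin ligase gene, were lower in the authors' deposited table. Ribosomal protein genes, heat shock genes and glycolysis genes were higher as groups in dual-targeted lines, and mitochondrially encoded genes were lower. In total 574 genes were higher and 354 lower in the authors' deposited table. The other genes named by size were Fam25c (2.41 ± 0.48), Mroh6 (1.96 ± 0.47), Adgrg6 (1.92 ± 0.34), Soga3 (1.89 ± 0.44) and Platr3 (1.89 ± 1.02) on the higher side of the authors' deposited table. On its lower side the authors' deposited table had Elovl7 (-1.78 ± 0.45), mt-Atp6 (-1.52 ± 0.57), Kcnt2 (-1.51 ± 0.51), Mir5125 (-1.49 ± 0.53) and Rnf157 (-1.46 ± 0.35).

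Ribosomal protein genes had a median log2 fold change of 0.51 (95% interval 0.47 to 0.61) between dual-targeted and single-targeted lines. They were higher at 43 of 87 members and lower at 0 (77 and 0 when adjusted over the list alone, list test adjusted p = 1.78e-32). Rps15 (0.94 ± 0.26, adjusted p = 0.00205) and Rps14 (0.87 ± 0.25, adjusted p = 0.0036) of the small subunit rose in the authors' deposited table. Of 11 heat shock genes, 7 were higher and 0 lower (9 and 0 when adjusted over the list alone, median 0.47, list test adjusted p = 3.18e-08). Hsp90ab1 (0.64 ± 0.21, adjusted p = 0.0125) was among them in the authors' deposited table. Of 19 glycolysis and hypoxia genes, 11 were higher and 1 lower (11 and 1 when adjusted over the list alone, median 0.65, list test adjusted p = 2.16e-06). The glycolytic genes Eno1 (1.22 ± 0.30, adjusted p = 7.25e-04) and Ldha (1.17 ± 0.28, adjusted p = 4.77e-04) rose in the authors' deposited table, and Vegfa (-1.21 ± 0.27, adjusted p = 2.37e-04), a growth factor induced by hypoxia, fell. Core pluripotency genes were higher at 3 of 14 members and lower at 0 (5 and 0 when adjusted over the list alone, median 0.28, list test adjusted p = 2.56e-04). Pou5f1 (1.02 ± 0.25, adjusted p = 7.25e-04) was among them in the authors' deposited table. Formative and primed pluripotency genes were higher at 2 of 12 members and lower at 0 (4 and 0 when adjusted over the list alone, median 0.37, list test adjusted p = 4.49e-23). Those past the threshold were Lef1 and Foxd3 (1.43 ± 0.31, adjusted p = 1.46e-04) in the authors' deposited table. Of 20 mitochondrially encoded genes, 1 was higher and 5 lower (2 and 6 when adjusted over the list alone, median -0.22, list test adjusted p = 0.00237). mt-Co2 (-1.12 ± 0.45, adjusted p = 0.0198) and mt-Co3 (-1.32 ± 0.56, adjusted p = 0.0224), subunits of cytochrome oxidase, fell in the authors' deposited table.

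ERK outputs were called higher in dual-targeted than in single-targeted lines (3 of 14 higher and 0 lower, 4 and 0 when adjusted over the list alone, median 0.21, adjusted p = 2.92e-04), with Spry2 (1.04 ± 0.26, adjusted p = 7.25e-04) in the authors' deposited table. The cell cycle list was called higher (2 of 28 higher and 0 lower, 2 and 0 when adjusted over the list alone, median 0.24, adjusted p = 6.92e-05), with Mcm2 (0.66 ± 0.27, adjusted p = 0.027) in the authors' deposited table. Wnt, BMP and Nodal targets were called higher (5 of 17 higher and 0 lower, 5 and 0 when adjusted over the list alone, median 0.07, adjusted p = 0.0212), with Id3 (1.72 ± 0.40, adjusted p = 2.37e-04) in the authors' deposited table. Immediate early genes were called higher (2 of 12 higher and 0 lower, 2 and 0 when adjusted over the list alone, median 0.11, adjusted p = 0.0118), with Myc (1.22 ± 0.48, adjusted p = 0.0152) in the authors' deposited table, but not without chromosomes 8, 14 and Y (adjusted p = 0.0946). That setting leaves out the members Ier2 and Junb, on chromosome 8, so the lost call does not show an effect of chromosome dosage. Small nucleolar RNA genes were called higher (7 of 56 higher and 0 lower, 9 and 0 when adjusted over the list alone, median 0.09, adjusted p = 2.56e-04), with Snora43 (1.35 ± 0.32, adjusted p = 3.26e-04) in the authors' deposited table. The 2-cell-like list was called higher on 2 uncertain multi-copy genes (0 of 2 higher and 0 lower, 2 and 0 when adjusted over the list alone, median 3.54, adjusted p = 0.00383). The integrated stress and unfolded protein response list was called lower (1 of 24 higher and 4 lower, 1 and 5 when adjusted over the list alone, median -0.20, adjusted p = 0.00315). Its members Chac1 (-1.38 ± 0.38, adjusted p = 0.00222) and Cebpb (-1.12 ± 0.51) fell in the authors' deposited table, while the chaperone gene Hspa5 (1.03 ± 0.26, adjusted p = 7.25e-04) rose. Replication-dependent histones were not called (5 of 60 higher and 0 lower, 6 and 0 when adjusted over the list alone, median -0.00, adjusted p = 0.436), and the linker histones Hist1h1a (1.13 ± 0.25, adjusted p = 1.46e-04) and Hist1h1e (1.47 ± 0.37) were higher in the authors' deposited table. Shorter genes were higher and longer genes lower (Spearman's rho across 9913 protein-coding genes, which are not independent replicates, -0.443), and with that trend taken out 341 genes were higher and 285 lower and the small nucleolar RNA and immediate early calls ended (adjusted p = 0.252 and 0.065). The Wnt, BMP and Nodal call ended at a preset correlation of 0.05 (adjusted p = 0.084), where the other 12 of the 13 held. Fisher's exact test of called members did not call 8 of the 13 lists, namely the integrated stress and unfolded protein response (adjusted p = 0.0528), core pluripotency (0.143), ERK outputs (0.143), small nucleolar RNA genes (0.143), formative and primed pluripotency (0.406), immediate early genes (0.406), the 2-cell-like list and the cell cycle (1 for both).

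**Figure D1:**
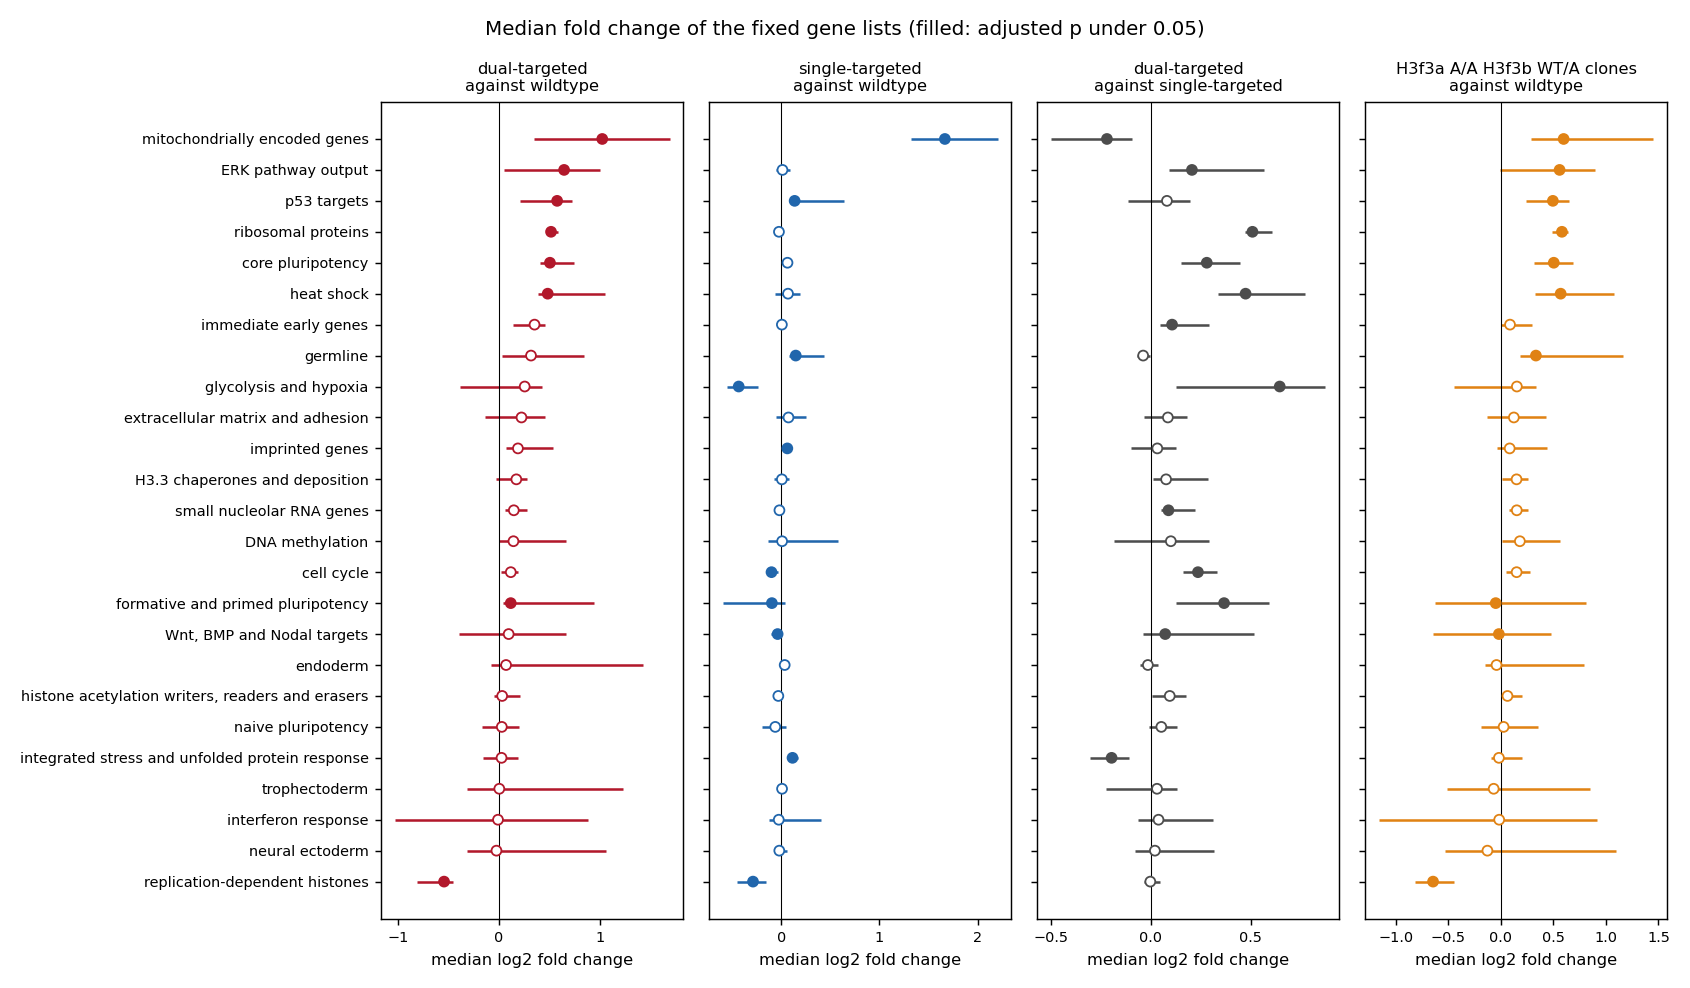
Median log2 fold change of each fixed gene list with 5 or more members (vertical axis) in the 4 comparisons, with bootstrap 95% intervals over members, filled where the list test has an adjusted p under 0.05. Ribosomal protein genes lie at 0.52 in dual-targeted and at -0.02 in single-targeted lines against wildtype.

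**Figure D2:**
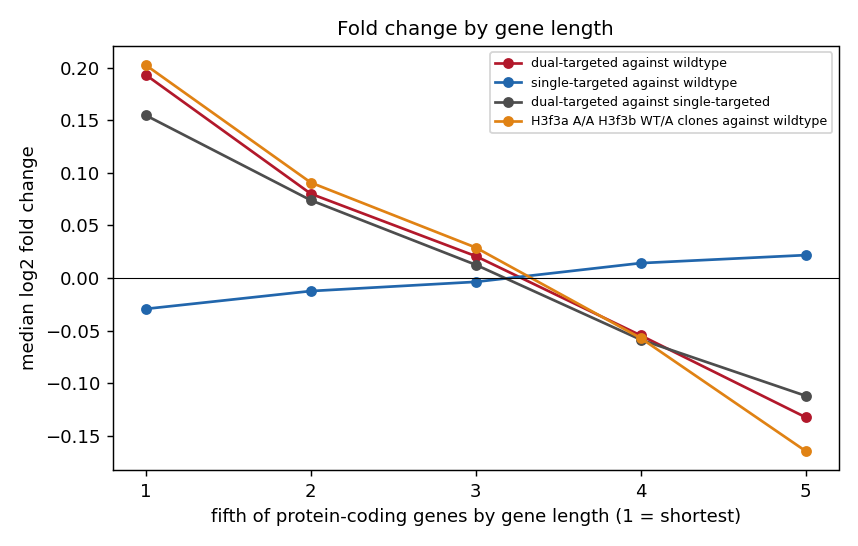
Median log2 fold change of protein-coding genes in 5 bins of gene length (horizontal axis, 1 is the shortest), with a line per comparison. In dual-targeted against single-targeted lines the medians run from 0.15 in the shortest bin to -0.11 in the longest.

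The 2 clones of the genotype H3f3a A/A H3f3b WT/A were compared with wildtype on their own, which leaves out the H3f3a WT/A H3f3b A/A line. The germline gene Stk31 (log2 fold change 3.65 ± 0.37 SE, adjusted p listed as 0), Catip (4.76 ± 0.52, adjusted p listed as 0) and Socs3 (3.40 ± 0.32, adjusted p listed as 0) rose in the authors' deposited table. Falls in the authors' deposited table included Prlr (-3.93 ± 0.61, adjusted p = 2.41e-09), the prolactin receptor, Lefty1 (-2.80 ± 0.29, adjusted p listed as 0), an inhibitor of Nodal signalling, and Acss1 (-3.89 ± 0.29, adjusted p listed as 0). The clones had 1416 genes higher and 1605 lower in the authors' deposited table. Without chromosomes 8, 14 and Y the balance turned, with 1357 higher and 1164 lower. The other genes named by size were Rbfaos (4.02 ± 0.36), Creb5 (4.00 ± 0.35), Adgrg6 (3.91 ± 0.45), Soga3 (3.71 ± 0.31) and Miat (3.26 ± 0.29) above wildtype in the authors' deposited table. Below wildtype the authors' deposited table had Lrrc31 (-3.83 ± 0.29), Sgo2b (-3.29 ± 0.39), Crispld1 (-2.91 ± 0.46), Ap3b2 (-2.82 ± 0.34) and Lrrc15 (-2.64 ± 0.40).

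Ribosomal protein genes were higher at 46 of 87 members and lower at 0 (64 and 0 when adjusted over the list alone, median 0.58, list test adjusted p = 9.96e-10). Of 25 p53 targets, 10 were higher and 1 lower (17 and 1 when adjusted over the list alone, median 0.50, list test adjusted p = 1.18e-07). Btg2 (1.11 ± 0.27, adjusted p = 9.36e-05) was among them in the authors' deposited table. Of 11 heat shock genes, 6 were higher and 0 lower (8 and 0 when adjusted over the list alone, median 0.57, list test adjusted p = 0.00139). Hspb1 (1.05 ± 0.27, adjusted p = 2.83e-04), a small heat shock protein, was among them in the authors' deposited table. Core pluripotency genes (7 of 14 higher and 0 lower, 9 and 0 when adjusted over the list alone, median 0.50, adjusted p = 0.0117) and ERK outputs (6 of 13 higher and 1 lower, 6 and 1 when adjusted over the list alone, median 0.56, adjusted p = 1.09e-06) were also called higher. So were mitochondrially encoded genes (8 of 20 higher and 0 lower, 12 and 0 when adjusted over the list alone, median 0.60, adjusted p = 3.08e-05) and germline genes (7 of 19 higher and 0 lower, 8 and 0 when adjusted over the list alone, median 0.33, adjusted p = 5.89e-07). Replication-dependent histone genes were higher at 0 of 61 members and lower at 31 (0 and 35 when adjusted over the list alone, median -0.64, list test adjusted p = 3.92e-07). Wnt, BMP and Nodal targets were called lower (5 of 17 higher and 4 lower, 5 and 4 when adjusted over the list alone, median -0.02, adjusted p = 0.00716), where Lefty1 and Lefty2 (-2.23 ± 0.30, adjusted p = 1.02e-12) fell and Id3 (1.44 ± 0.36, adjusted p = 1.45e-04) rose in the authors' deposited table. For formative and primed pluripotency genes the median lay below 0 while the test called them higher (4 of 12 higher and 3 lower, 4 and 4 when adjusted over the list alone, median -0.05, adjusted p = 0.00139), with Lef1 at 1.93 ± 0.23 and Foxd3 at 2.35 ± 0.34 in the authors' deposited table. On ranks neither of these lists was called, with adjusted p = 0.977 for the formative list and 0.977 for the Wnt, BMP and Nodal list, and by Fisher's exact test, which counts calls in either direction, the latter list was called with more members higher than lower (adjusted p = 0.0105). At a preset correlation of 0.05 all 10 calls held, while Fisher's exact test of called members did not call germline (adjusted p = 0.146) and mitochondrially encoded genes (0.054).

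The single-targeted and dual-targeted comparisons with wildtype were then read side by side to see which genes moved in both. Acss1 and Lrrc31 fell and Plk2 and Peg10 rose in both, by the values above. Of 15966 genes with a p in both of the authors' deposited tables, 158 were higher and 157 lower in both, against 23.3 and 23.0 for independent lists. Of the 157 lower genes, 54 lie on chromosome 8 and 13 on chromosome 14, and without chromosomes 8, 14 and Y 149 genes were higher and 90 lower in both, against 22.9 and 10.4 for independent lists. Among those called in both, 1 gene went in opposite directions, the predicted gene Gm10060, which was higher in dual-targeted lines (0.70 ± 0.24) and lower in single-targeted lines (-1.10 ± 0.28) in the authors' deposited tables and was named after its values were seen. The 315 genes were 71.1% of the 443 that single-targeted lines called among the genes tested in both. The direct comparison in the authors' deposited table called 30 of the 315, and 29 of these lay further from wildtype in dual-targeted lines. Both comparisons use the same wildtype libraries, which alone gave a simulated correlation of the signed test statistic across genes of 0.448 and a covariance of 0.447, beside observed values of 0.503 and 1.94. The same-sign share was 64.9% against 64.7% simulated. In the simulation 0 genes were called in both. With no effect in any simulated group almost no gene can be called, so this 0 is no yardstick for the 315. Since the wildtype group could not be divided here, part of the excess may come from the shared controls, and the lower genes include the difference of chromosome 8. The descent of the mutant lines is not given in the sources used here. Changes that lines share by descent can therefore not be told apart from effects of the substitution.

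Fold changes were also read by chromosome, since clonal stem cell lines can gain or lose chromosome material. Genes of chromosome 8 were lower than wildtype in every mutant group, and genes of a stretch of chromosome 14 were lower in the H3f3a A/A H3f3b WT/A clones. On chromosome 8 the median log2 fold change in the authors' deposited table was -0.32 (95% interval -0.37 to -0.28) over 625 genes in dual-targeted lines, with 30 genes higher and 230 lower. In single-targeted lines it was -0.21 (-0.23 to -0.18) over 648 genes, with 3 higher and 83 lower, in the authors' deposited table. Between dual-targeted and single-targeted lines it was 0.02 (-0.01 to 0.04). Rebuilt group means, which are not shrunken as the deposited fold changes are, put chromosome 8 genes at 71.9% of wildtype in single-targeted lines, 76.4% in the clones and 74.2% in the H3f3a WT/A H3f3b A/A line. On chromosome 14 the median was -0.51 (-0.59 to -0.36) in the clones, -0.25 (-0.30 to -0.18) in dual-targeted lines and -0.06 (-0.08 to -0.05) in single-targeted lines. In the clones, the medians of 10 segments of equal gene number ran from 0.07 to -1.09, and the 5 segments between 45219717 and 74947876 (GRCm38) lay between -0.62 and -1.09. The 199 genes of that stretch stood at 49.4% of wildtype in the clones, 75.7% in single-targeted lines and 98.5% in the H3f3a WT/A H3f3b A/A line. In dual-targeted against wildtype, the other autosomes and chromosome X had medians from -0.02 to 0.08. Of the genes named above as lower, Cers1, Klf2, Kctd19, Mcm5 and Sgo2b lie on chromosome 8, while Zic2 (chromosome 14, 122475435 to 122479852) lies outside the low stretch of chromosome 14. These medians carry no spread between libraries, and the intervals cover the spread between genes only.

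**Figure D3:**
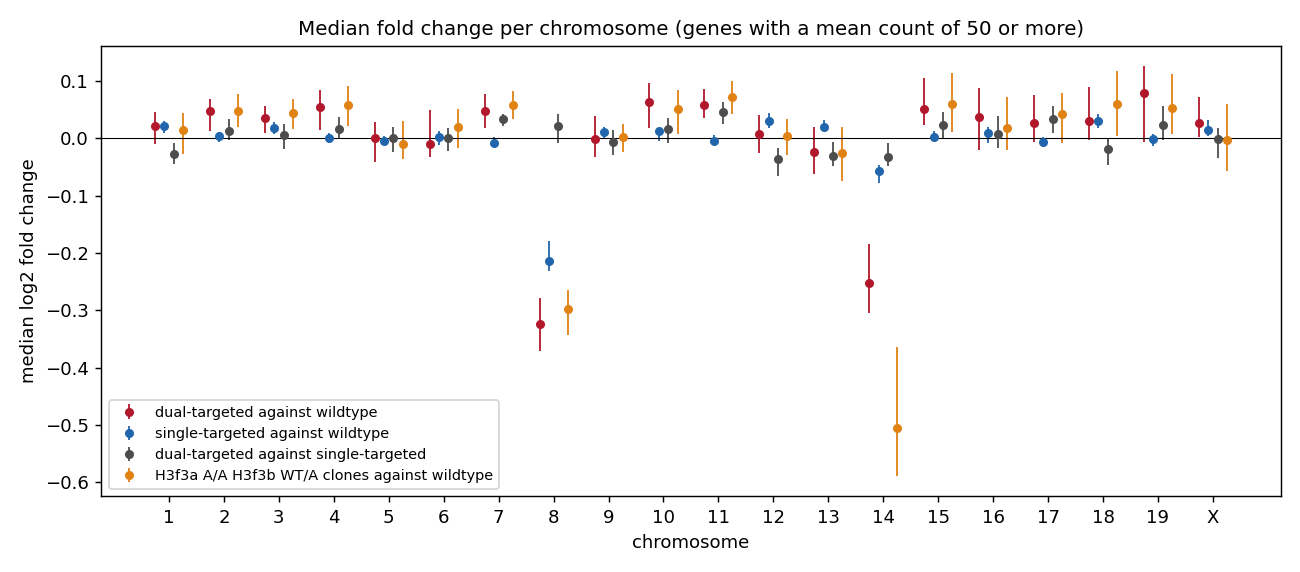
Median log2 fold change of the genes of each chromosome (horizontal axis) with a mean count of 50 or more, in the 4 comparisons, with bootstrap 95% intervals over genes. Chromosome 8 lies at -0.32 in dual-targeted and -0.21 in single-targeted lines against wildtype, and chromosome 14 at -0.51 in the clones.

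**Figure D4:**
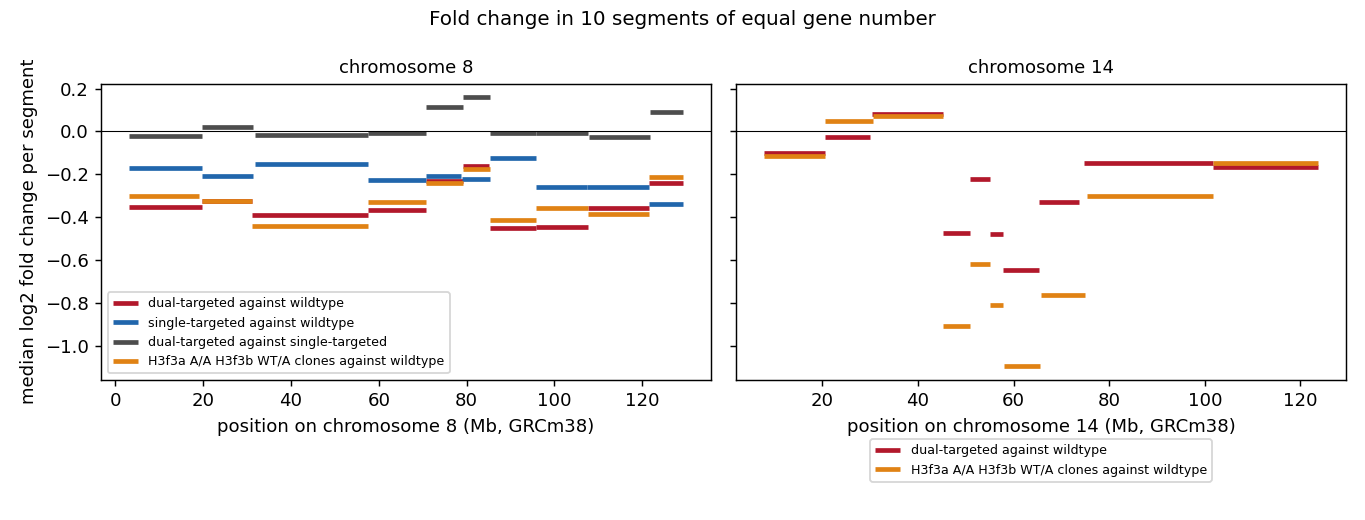
Median log2 fold change in 10 segments of equal gene number along chromosomes 8 and 14 (horizontal axis, position in Mb, GRCm38), with a colour per comparison and only the comparisons with wildtype that include the clones drawn for chromosome 14. In the clones, chromosome 14 segments between 45219717 and 74947876 lie between -0.62 and -1.09.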

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

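The test for mature RNA in the labelled fraction was chosen only after the result was seen, and the test for gene length after the data were seen but before its own result. Single-targeted and dual-targeted lines share a wildtype group, and the direct comparison of the authors' deposited table tested the difference between them. That test called 13 lists, which is why they stand here: medians were 0.28 for core pluripotency, 0.37 for formative and primed pluripotency, 3.54 for the 2-cell-like list, 0.51 for ribosomal proteins and 0.47 for heat shock. They were 0.11 for immediate early genes, 0.21 for ERK outputs, 0.0716 for Wnt, BMP and Nodal targets, 0.24 for the cell cycle, 0.65 for glycolysis and hypoxia and 0.0879 for small nucleolar RNA genes. Medians below 0 were -0.20 for the integrated stress and unfolded protein response and -0.22 for mitochondrially encoded genes. Gm26917 (chromosome 17, 39843013 to 39846341), annotated as a long intergenic RNA gene, differed in the same test, with a log2 fold change of 1.07 ± 0.21 (SE, adjusted p = 2.42e-05) in the authors' deposited table. Its share of the summed reconstructed means was 32.3% in wildtype, 29.3% in single-targeted and 46.1% in dual-targeted lines. Together with its neighbour Gm42418 (chromosome 17, 39846958 to 39848788) the share was 34.7%, 31.4% and 49.4% in the same order. Which RNA these reads come from was not tested.

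In the authors' deposited table of dual-targeted against wildtype, 5 genes had a fold change and no p, so they did not enter that comparison. They were Thbs1 (4.69 ± 1.49), Tagln (0.26 ± 0.53), Mir6236 (-0.00 ± 0.38), mt-Rnr1 (0.14 ± 0.42) and mt-Rnr2 (0.15 ± 0.43) in the authors' deposited table. DESeq2 leaves the p empty where it flags an outlying count, so these values may rest on a single library. mt-Rnr1 had a mean count of 1100 here, 1198 in dual-targeted against single-targeted and 141 in single-targeted against wildtype. For mt-Rnr2 the means were 1970, 2213 and 266 in the same order. The shrunken fold changes of mt-Rnr1 and mt-Rnr2 therefore do not show an unchanged level.

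The first pattern weighed is the rise of ribosomal protein genes in dual-targeted lines, which are short genes in a comparison where short genes rose. With the gene length trend taken out, their median against single-targeted lines was 0.37 (95% interval 0.29 to 0.42, adjusted p = 5.99e-22). The trend as estimated therefore left part of the rise in place. It was estimated from shrunken fold changes of all protein-coding genes, and highly expressed genes such as these may be shrunken less. The trend taken out may thus be too small for them, so gene length as the whole cause stays open. Mature RNA carried into the labelled fraction stays open: features inside introns, which mature RNA lacks, lay below their host genes by a median log2 difference of -0.0408 (interval -0.0618 to -0.0174), as more mature RNA in dual-targeted lines would give. A difference in transcription linked to the third mutant allele may also account for the rise, and it was not tested apart from clone, since lines and allele number go together. The intronic difference covers the comparison as a whole. Mature RNA therefore stays open for the other lists called higher there too, and was not tested for them.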

How the results depend on the processing

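The settings without chromosomes 8, 14 and Y and with the gene length trend taken out were chosen only after the results were seen. No paired analysis was possible because the tables hold no values per library, and for the same reason leave-one-out fits, a replicate block and other splits of the samples were not run. The clones alone stood in for the 3 dual-targeted lines. There 115 of 124 named genes kept their direction and side of the threshold, 5 became weaker and 4 stronger. The 2 clones are among the 3 dual-targeted lines and were set against the same wildtype libraries, so this agreement is largely built in. With fold changes centred on the median, 132 of 133 named genes in dual-targeted against wildtype and 123 of 124 in single-targeted against wildtype kept direction and side. So did 121 of 124 in dual-targeted against single-targeted and 128 of 128 in the clones, and none of the named genes changed direction. The medians taken off were 0.0137, -0.0032, 0.0145 and 0.0142 in the same order. These are small beside the standard errors, so few calls could change. Adjusting over every gene with a p gave 523 genes higher and 318 lower in dual-targeted against single-targeted. It ended 3 of the 67 calls among the 124 named genes there (Mcm7, Peg13 and Sall4), and no named call in the other comparisons. Ranks ended the call of the formative list in each of the 3 comparisons with wildtype, and that of Wnt, BMP and Nodal targets in single-targeted lines and the clones against wildtype and in dual-targeted against single-targeted. Lists that were not called gained a call too. In dual-targeted against wildtype ranks added the 2-cell-like list (adjusted p = 0.0472), germline (0.00777), imprinted (0.0287), immediate early (0.0143) and small nucleolar RNA genes (0.0193). There the 2-cell-like and germline lists were also called without chromosomes 8, 14 and Y, and these and imprinted genes with the length trend out. Ranks added small nucleolar RNA genes in the clones, leaving out these chromosomes added extracellular matrix and adhesion in single-targeted against wildtype, and taking out the trend added H3.3 chaperones in dual-targeted against single-targeted. Fisher's exact test, which counts calls in either direction, added the interferon response and glycolysis and hypoxia in dual-targeted lines and the clones against wildtype. Unknown depth limits what the absence of a call means.

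At an adjusted p under 0.01, which calls fewer genes by construction, genes higher and lower were 1032 and 968 in dual-targeted against wildtype, 129 and 113 in single-targeted against wildtype, 178 and 88 in dual-targeted against single-targeted and 756 and 964 in the clones, with 163 genes shared. At an adjusted p under 0.1 they were 337 and 358 in single-targeted against wildtype and 896 and 644 in dual-targeted against single-targeted. With an absolute log2 fold change of 1 or more they were 640 and 621, 130 and 71, 135 and 111, and 530 and 760, in the same order of comparisons. Without chromosomes 8, 14 and Y, 119 genes were lower in single-targeted lines, and with the length trend out 341 were higher in dual-targeted against single-targeted. Fisher's exact test of called members called 5 lists in single-targeted against wildtype and 5 in dual-targeted against single-targeted, ending 6 of 11 and 8 of 13 calls, and 1 call in dual-targeted against wildtype and 2 in the clones, and the cause was not tested. In the clones, the formative list changed from higher to lower on ranks, where it was not called (adjusted p = 0.977). There the Wnt, BMP and Nodal list changed from lower to higher with Fisher's exact test (adjusted p = 0.0105), since 5 members were called higher and 4 lower. With genes of a mean count of 10 or more, the difference of chromosome 8 from the other chromosomes was -0.29 in dual-targeted, -0.13 in single-targeted lines and -0.28 in the clones against wildtype. That of chromosome 14 was -0.20 in dual-targeted lines and -0.36 in the clones against wildtype, and -0.0206 in dual-targeted against single-targeted. With a mean count of 100 or more, chromosome 8 was at -0.25 in single-targeted lines. The cause of these shifts was not tested.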

Other observations

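The tests for loss of 1 copy of chromosome 8 or of part of chromosome 14, for fewer cells in S phase and for gene length at the histone genes were chosen only after the results were seen, and so was a bound in the tests of whole chromosomes. Gene length went with the fold change in each comparison. Across protein-coding genes, which are not independent replicates, Spearman's rho was -0.293 in dual-targeted against wildtype, 0.162 in single-targeted against wildtype and -0.309 in the clones. In dual-targeted lines 457 of the 2006 shortest genes were higher and 121 lower, while 126 of the 2004 longest were higher and 382 lower, in the authors' deposited table. Genes of the annotation type TEC, unspliced models awaiting experimental support, were higher at 20 and lower at 97 of 600 in dual-targeted lines, and higher at 5 and lower at 4 of 670 in single-targeted lines. Features inside introns lay below their host genes in dual-targeted against wildtype, by a median log2 difference of -0.10 (95% interval -0.12 to -0.07) over 563 pairs. In single-targeted lines the difference was -0.00 (-0.01 to 0.01) over 627 pairs.

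Y-linked genes moved apart between lines in the reconstructed means, which carry no error. Uty stood at 596 normalized counts in wildtype, 39.5 in the clones and 669 in the H3f3a WT/A H3f3b A/A line. Ddx3y stood at 470 in wildtype, 92.3 in the clones and 841 in that line. Uba1y was higher in the clones and in single-targeted lines, with 18.5 in wildtype, 227 in single-targeted lines and 165 in the clones. This does not cover the H3f3a WT/A H3f3b A/A line. By shrunken fold changes, the authors' deposited table called Uty lower (-0.28 ± 0.57, adjusted p = 0.0207) and Uba1y higher (3.12 ± 0.43, adjusted p = 9.00e-12) in the clones against wildtype.

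The second pattern weighed is the lower genes of chromosomes 8 and 14, where on chromosome 8 all 10 segments lay below other chromosomes in dual-targeted lines, as a difference in chromosome number would give, and random gene sets matched on length and mean count reached no lower than -0.0533, beside a median of -0.32. Loss of 1 of 2 copies in all mutant cells would leave a level near that of the chromosome 14 part in the clones, itself only a candidate for such a loss. The lowest of the 3 mutant groups stood at 71.9% of wildtype (95% interval 70.3 to 74.0), which argues against that loss. An extra copy in the wildtype cells or a loss in part of the cells of each line may account for the lower level and stays open. Neither was held to an expected level. On chromosome 14 in the clones, 8 of 10 segments lay below, matched sets reached -0.10 beside -0.51, and segments at the level of other chromosomes argue against a whole-chromosome change. Loss of 1 copy of a part may account for it, since that part stood at 49.4% of wildtype (95% interval 46.7 to 53.1) in the clones and 98.5% in the H3f3a WT/A H3f3b A/A line, while an effect of the substitution itself was not tested. The single-targeted group, in which 1 of 2 lines was H3f3a A/A, stood at 75.7%, so a loss shared by the H3f3a A/A lines is a candidate explanation that values per line would be needed to test.

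The third pattern weighed is the fall of replication-dependent histone genes. The gene length trend would raise genes of their lengths in dual-targeted lines, by 0.25, so it argues the other way. Fewer cells in S phase may account for the fall in single-targeted lines, where 14 S-phase genes had a median of -0.17 (95% interval -0.45 to -0.06), and the 12 outside chromosome 8 had -0.12 (-0.33 to -0.02). In dual-targeted lines the median was 0.12 (-0.13 to 0.26), or 0.14 (0.06 to 0.34) outside chromosome 8 and 0.0390 (-0.0476 to 0.24) with the gene length trend also taken out, so it stays open there, although the 14 genes were higher than in single-targeted lines (0.32, 0.24 to 0.41) and the clones stood at 0.15 (-0.04 to 0.40). An effect of the substitution on histone genes stays open and was not tested.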
